A study of Mus musculus with 9 samples.

How the data were processed

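Colon RNA of C57BL/6J mice was measured by sequencing of poly-A selected mRNA in 9 libraries, 3 from untreated animals (Normal), 3 from animals given 2.5% dextran sulfate sodium in the drinking water (DSS), and 3 from animals given the same DSS and royal jelly acid (RJA). The labels give no dose or schedule of RJA, no day of sampling, and do not say that each library came from a separate mouse, so every p-value below measures the spread between samples. Groups were taken from the sample titles. The strand setting of the libraries is not stated, so reads from overlapping genes on opposite strands may have been counted together.

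The values are FPKM per gene as deposited by the submitters, 1 column per library, with a gene length per gene. Per the submitters' processing notes, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR 3.22.5 were used with the mm10 build; the role and settings of each tool are not given. The deposited FPKM values multiplied by gene length were whole multiples of 1 step per library (within 0.01, 100% of the values above 0), so fragment counts could be rebuilt. The rebuilt totals ran from 15545433 to 17129843 fragments per library. The library size implied by the step differed from the rebuilt total by a factor of 0.9217 to 1.079, so the submitters' values carry a scaling factor per library. The rebuilt counts were used for the depth and for 1 alternative fit. The median tested gene had 400.2 rebuilt fragments averaged over the libraries.

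The table held 54532 genes, of which 54495 had their identifier in the GENCODE vM21 annotation and 53585 (98.3% of those) had the same chromosome, start and end there. Symbols shared by more than 1 identifier (100 symbols, 203 identifiers) were kept apart by identifier. Genes with a mean FPKM of at least 0.5 over the 9 libraries were tested, 15804 in all. Of these, 344 had a length under 200 bases, where FPKM is imprecise. Reads shared between close paralogs (guanylate-binding proteins, Gsdmc genes, hemoglobins, immunoglobulins) cannot be assigned from the table.

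Log2(FPKM + 1) values were fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group and all 9 libraries in 1 fit, followed by moderated statistics with a trend of the variance on the mean. The added 1 shrinks fold changes of genes with low FPKM. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each of 3 comparisons, two-sided, with no minimum fold change. The fit pools the spread of the 3 groups. The median SD of the log2 values was 0.143 in Normal, 0.221 in DSS and 0.257 in RJA, so the pooled spread is wider than that of Normal. RJA against DSS is thus tested with a spread that includes the less variable Normal libraries, which can make its p-values too small.

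Before the data were examined, 44 gene lists for the tissue and the treatment were fixed from background knowledge, and 42 had at least 4 tested members. Each was tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison. Camera was run again with the correlation estimated per list, and fry tested whether the genes of a list moved 1 way on balance. Members called after adjustment within their list are given as adjusted over the list alone. Genes were named by a rule fixed at the same time. It took 8 genes from the series title and pathway (Gbp3, Nlrp3, Casp1, Casp4, Pycard, Gsdmd, Il1b, Il18). It added, per comparison and direction, the 8 protein-coding genes with the largest change among those called, with no overlap between the libraries of both groups and a mean FPKM of at least 5 in the higher group, predicted genes left out. Where fewer than 8 qualified, those with the smallest p filled up, as values only. It added up to 4 members with the smallest p of each list described. The text leaves out 3 of the genes this rule chose, and its counts of named genes include them. For DSS against Normal, the hypoxia, circadian clock, and mast cell and eosinophil lists were chosen for description after their values were seen.

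DSS against Normal and RJA against DSS share the DSS libraries, which by itself makes their changes run in opposite directions. The overlap of the called genes was therefore set beside 100 simulated draws of groups with no change, and, added after seeing the data, beside 100 draws with the measured DSS change kept and RJA set to the DSS mean. In addition, each DSS library was held out in turn. Genes were called between Normal and the other DSS libraries, in a fit whose spread included the RJA libraries. Over those genes, the median distance from the held-out DSS library to the RJA mean was divided by the median distance to the Normal mean.

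The test was run on simulated data with the same genes and group sizes and 200 seeded genes. With the pooled spread, 20.9% of genes changed by 2 times, 58.2% of genes changed by 4 times and 77.3% of genes changed by 8 times were called in DSS against Normal, with 4 false calls. The shares were 34.3%, 77.6% and 87.9% with 12 false calls in RJA against DSS, and 41.8%, 65.7% and 78.8% with 5 false calls in RJA against Normal. Each share rests on 66 or 67 genes. All groups were simulated from the Normal means with the same spread per gene, so the comparisons differ only by random draw. Their shares therefore do not rank the comparisons by power. Libraries lying apart from their group were not simulated. Among the 42 lists, camera called 1 with no list changed in DSS against Normal and 0 in the other 2 comparisons. The simulated noise was independent between genes, so this does not show how often camera calls lists whose members vary together.

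Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, TPM scaling, a fit of only the 2 groups compared, limma array weights, limma-voom on the rebuilt fragments, the sample number as a block, a log2 fold change of at least 1, and leaving out each library. Gene-by-gene array weights, and all alternatives for the held-out measure, were added after seeing the data. Leaving out a library leaves 2 in its group and the pooled spread of the rest. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.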

Results

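Gene expression in mouse colon was measured as FPKM, fragments per kilobase of gene scaled to library size, in 9 libraries. There were 3 groups of 3 libraries: Normal (untreated), DSS (2.5% dextran sulfate sodium in the drinking water, which injures the colon lining and causes colitis) and RJA (the same DSS with royal jelly acid). Depth, rebuilt from the FPKM values, was 15545433 to 16907682 fragments in Normal, 16135556 to 17050196 in DSS and 16669466 to 17129843 in RJA. The first principal component held 70% of the variance. Normal libraries lay at -53.3, -48.7 and -52.3 on it, DSS libraries 1 to 3 at 81.9, 19.8 and 76, and RJA libraries 1 to 3 at -53.6, -22.3 and 52.6. RJA 3 thus lay between DSS 2 and DSS 3, and DSS 2 lay nearest to Normal among the DSS libraries.

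DSS against Normal asks what colitis changed in the colon. S100a9, a subunit of the neutrophil protein calprotectin (chromosome 3, 90692632 to 90695721), went from 0.633 ± 0.412 FPKM in Normal to 447.3 ± 211 in DSS (SD, n = 3 each), a log2 fold change of 8.02 (SE 1.81, limma adjusted p = 0.0254). S100a8, its partner, rose by 7.77 (SE 1.86, adjusted p = 0.0279), the acute phase gene Saa3 by 6.82 (SE 1.64, adjusted p = 0.0281) and the T-cell attracting chemokine Cxcl9 by 5.89 (SE 0.90, adjusted p = 0.0129). Hp, Chil3, Retnlg and Il1b rose by 5.85, 5.62, 5.43 and 5.41. Cyp2c55, a cytochrome P450, went from 297.5 ± 105 FPKM to 0.068 ± 0.0616 (log2 fold change -8.07, SE 1.29, adjusted p = 0.014). The chloride-bicarbonate exchanger Slc26a3 (-5.31), the gasdermin Gsdmc3 (-5.34), the calcium-binding S100g (-5.23), Hao2 (-5.05), Cyp2c68 (-4.77), the brush border protease Mep1a (-4.73) and Selenbp1 (-4.70) also fell. The libraries of DSS and Normal do not overlap for any of these 16 genes, by the rule that chose them.

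In all, 1639 genes were higher and 1776 lower in DSS, 3415 of 15804 tested (21.6%). Leaving out 1 library brought the higher and lower counts to 43 and 14 (without Normal 1), 110 and 44 (Normal 2), 68 and 21 (Normal 3), 124 and 46 (DSS 1), 112 and 37 (DSS 3), 963 and 1088 (RJA 2), 2368 and 2669 (DSS 2), and 2705 and 2814 (RJA 3). Without RJA 1 the counts were 2216 and 2251. No gene called in both the full and a reduced set changed sign, and 57 of the 3415 genes kept their call without Normal 1. Of 132 named genes called, 9 kept the call whichever library was left out: Zbp1, B2m, Ccl8, Il22, Nkg7, Gzma, Slpi, Duoxa2 and Ascl2.

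Immune gene groups were higher in DSS. DSS 2 lay below DSS 1 and DSS 3 for interferon-gamma genes (1.451, against 2.473 and 3.073) and type I interferon genes (0.568, against 1.122 and 2.105). Of 27 interferon-gamma response and antigen presentation genes, 24 rose and 3 did not pass (27 rose adjusted over the list alone, camera adjusted p = 7.9e-14), among them B2m (1.77, SE 0.19), Socs1 (3.10, SE 0.38) and the tryptophan-degrading Ido1 (4.46, SE 0.74). Of 25 inflammatory cytokines and chemokines, 15 rose (20 adjusted over the list alone, camera adjusted p = 2.74e-10), with Ccl8 (3.16, SE 0.19), Il22 (3.94, SE 0.44), Nos2 (4.61, SE 0.58) and the eosinophil attractant Ccl11 (3.79, SE 0.56). Of 23 T and NK cell markers, 19 rose (21 adjusted over the list alone, camera adjusted p = 2.74e-10), including Nkg7 (2.23), Klrd1 (1.88), Gzma (3.43) and Cd4 (1.31). Of 21 monocyte and macrophage markers, 16 rose (19 adjusted over the list alone, camera adjusted p = 2.72e-09), with C1qb, Ms4a7, C1qa and Csf1r between 1.26 and 1.85. Of 18 neutrophil markers, 10 rose (13 adjusted over the list alone, camera adjusted p = 2.72e-06), including Ltf (3.93) and Ly6g (1.58). Ly6g was already at 210.7 FPKM in Normal, where S100a9 was at 0.633, so it may not track neutrophils in these libraries. Of 19 Toll-like receptor and NF-kB genes, 9 rose (14 adjusted over the list alone, camera adjusted p = 2.72e-06), with Vcam1 (2.76), Icam1 (2.46), Myd88 (1.41) and Tnfaip3 (1.15). For each of these 6 lists, adjusted p = 0.408 with an estimated correlation. Of 24 type I interferon genes, 10 rose (16 adjusted over the list alone, camera adjusted p = 5.69e-07, adjusted p = 0.411 with an estimated correlation), such as Ifit2 (2.45), Usp18 (1.98), Bst2 (1.71) and Ifi27l2a (2.51). Of 13 plasma cell markers, 5 rose (7 adjusted over the list alone, camera adjusted p = 0.00102, adjusted p = 0.408 with an estimated correlation), including the immunoglobulin genes Igkc (1.47) and Igha (1.46).

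Many epithelial gene groups and smooth muscle markers were lower in DSS. DSS 2 stood apart from DSS 1 and DSS 3 in several. It lay at -0.846 for colonocyte markers (-2.981 and -2.665 in the others), -0.543 for tight junction genes (-1.543 and -1.373), -1.529 for xenobiotic metabolism (-3.029 and -2.927) and -0.32 for cholesterol biosynthesis (-1.08 and -0.952). Of 20 absorptive colonocyte markers, 6 fell (8 adjusted over the list alone, camera adjusted p = 0.000255, adjusted p = 0.514 with an estimated correlation), among them Guca2a (-4.45, SE 0.74) and Guca2b (-2.30, SE 0.39), which encode guanylin peptides, and the monocarboxylate carrier Slc16a1 (-1.70, SE 0.34). Of 16 goblet cell markers, 2 fell, the transcription factors Creb3l1 (-2.34) and Atoh1 (-3.51), and Retnlb rose (3.97); the counts adjusted over the list alone were the same, and camera gave adjusted p = 0.0106 (0.0601 without DSS 1, adjusted p = 0.581 with an estimated correlation). For this list DSS 2 lay at 0.261, above the Normal libraries, and DSS 1 and DSS 3 at -2.313 and -1.958. Of 21 tight junction and adhesion genes, 7 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.000765, adjusted p = 0.514 with an estimated correlation), with Cldn2 (-3.76), Cldn15 (-2.17), Cldn8 (-4.66) and Ocln (-2.15). Of 23 xenobiotic metabolism genes, 13 fell (20 adjusted over the list alone, camera adjusted p = 2.35e-08, adjusted p = 0.408 with an estimated correlation), including Gstm3 (-4.06) and Ugt1a7c (-1.70). Of 21 cholesterol biosynthesis genes, 7 fell (12 adjusted over the list alone, camera adjusted p = 9.94e-06, adjusted p = 0.418 with an estimated correlation), with Dhcr7 (-1.87), Stard4 (-1.75) and Mvk (-0.98). Of 17 smooth muscle markers, 15 fell (15 adjusted over the list alone, camera adjusted p = 1.51e-07, adjusted p = 0.408 with an estimated correlation), with Actg2 (-2.32), Synpo2 (-1.56), Smtn (-1.40) and Pgm5 (-0.89). Of 17 stem and progenitor markers, 9 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 0.000359, adjusted p = 0.408 with an estimated correlation), with the stem cell factor Ascl2 at -2.04 (SE 0.23). Of 13 mitochondrially encoded genes, 2 fell (11 adjusted over the list alone, camera adjusted p = 0.000118, adjusted p = 0.408 with an estimated correlation), and the mitochondrial share of fragments was 3.95% to 5.71% in Normal, 2.63% to 3.01% in DSS and 2.95% to 4.40% in RJA.

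Repair, defence and stress genes were higher in DSS. Of 14 epithelial antimicrobial genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00872, 0.0742 without DSS 2, adjusted p = 0.408 with an estimated correlation), with the protease inhibitor Slpi (3.77, SE 0.36) and the peroxide-generating pair Duoxa2 (2.12, SE 0.23) and Duox2 (1.73, SE 0.33). Of 19 wound-associated epithelium genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.000588, adjusted p = 0.408 with an estimated correlation), with Ly6a (2.01), Sprr1a (2.87) and Anxa1 (1.62). Of 13 matrix proteases and inhibitors, 7 rose (10 adjusted over the list alone, camera adjusted p = 2.54e-05, adjusted p = 0.411 with an estimated correlation), with Mmp10 (5.10), Plaur (3.14), Adamts4 (2.92) and Mmp14 (1.63). Of 17 endoplasmic reticulum stress genes, 12 rose (14 adjusted over the list alone, camera adjusted p = 3.73e-07, adjusted p = 0.408 with an estimated correlation), with the stress transcription factor Xbp1 at 0.86 (SE 0.13) and Chac1 at 0.82 (SE 0.14). All 5 tested erythroid markers rose (5 adjusted over the list alone, camera adjusted p = 0.000142, adjusted p = 0.408 with an estimated correlation), including Hbb-bs (2.62) and Alas2 (1.34).

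**Figure D1:**
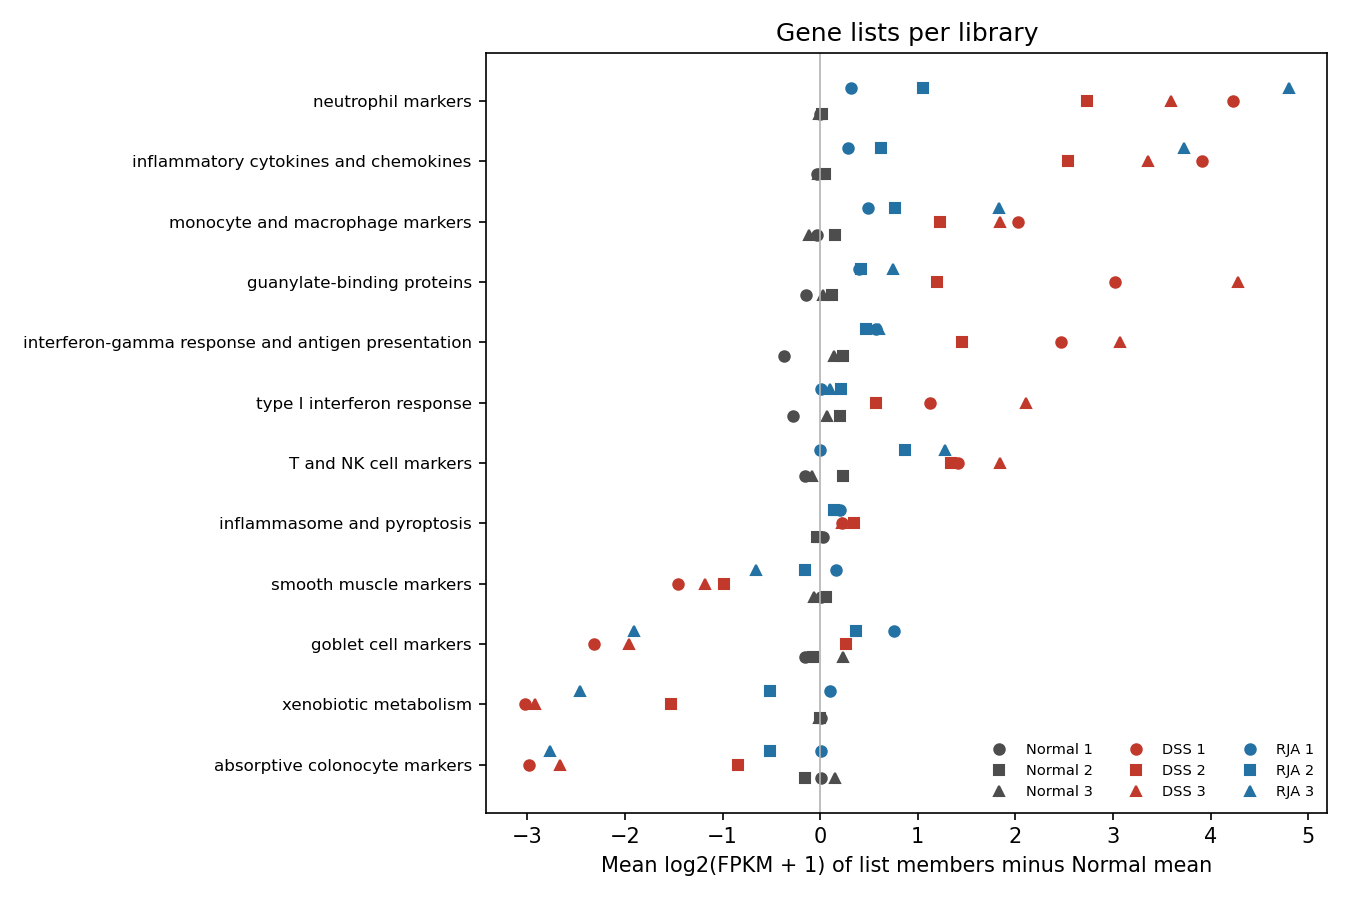
Mean log2(FPKM + 1) of the members of 12 gene lists in each library, minus the mean of the Normal libraries (x axis, log2 units), with groups by colour and libraries by marker. RJA 3 lay at 4.81 for neutrophil markers, above the DSS libraries (2.74 to 4.23), and at 0.60 for interferon-gamma genes, below them (1.45 to 3.07).

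The series title names Gbp3, pyroptosis (lytic, inflammasome-driven cell death) and the NLRP3 inflammasome. Gbp3, an interferon-induced GTPase gene (ENSMUSG00000028268, mm10 chromosome 3, 142560026 to 142573209, plus strand), had 8.63 ± 2.01 FPKM in Normal, 107.5 ± 94 in DSS and 13.47 ± 3.46 in RJA (SD, n = 3 each). It rose in DSS by 3.06 (SE 0.64, limma adjusted p = 0.0228), with all 3 DSS libraries above all Normal ones. Between RJA and DSS the log2 difference was -2.48 (SE 0.64, adjusted p = 0.141), which did not pass, although the RJA libraries (10.17, 13.15 and 17.08 FPKM) all lay below the lowest DSS library (25.65 FPKM). Against Normal, RJA differed by 0.58 (SE 0.64, adjusted p = 0.813). Of 11 guanylate-binding proteins, Gbp3 included, 9 rose in DSS (11 adjusted over the list alone, camera adjusted p = 2.93e-06, adjusted p = 0.408 with an estimated correlation), among them Gbp5 (3.87), Gbp2 (3.66) and Gbp8 (2.43). For this list DSS 2 lay at 1.197, and DSS 1 and DSS 3 at 3.024 and 4.286. In RJA against DSS, 0 passed over all genes and 11 were lower adjusted over the list alone (camera adjusted p = 7.6e-08, adjusted p = 0.52 with an estimated correlation), with Gbp5 at -3.08 and Gbp8 at -1.80. These genes are close paralogs, so reads may be shared between them. The Gbp3 call in DSS against Normal was lost without Normal 1, 2 or 3 (adjusted p = 0.0846, 0.0663 and 0.0803) and without DSS 1 or DSS 3 (0.0829 and 0.0641), and its p ran from 0.000116 to 0.0846 over all alternatives. In RJA against DSS its p ran from 0.000264 to 0.391, and it passed without DSS 2 (0.0119) and without RJA 3 (0.0391).

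Pyroptosis genes did not move as 1 group in DSS. Of 24 inflammasome and pyroptosis genes, 7 rose, 3 fell and 14 did not pass (8 and 5 adjusted over the list alone, camera adjusted p = 0.577, with a median of -0.18 and a mean of 0.26 that differ in sign). Il1b rose by 5.41 (SE 1.46, adjusted p = 0.0362), the lipopolysaccharide-sensing caspase gene Casp4 by 1.19 (SE 0.20, adjusted p = 0.0158), the nucleic acid sensor Zbp1 by 2.43 (SE 0.26, adjusted p = 0.00703) and the pyrin gene Mefv by 2.46 (SE 0.54, adjusted p = 0.0241). The adaptor Pycard fell by 1.46 (SE 0.35, adjusted p = 0.0284), and Naip6 fell by 1.65 (SE 0.33, adjusted p = 0.0219). Nlrp3 (chromosome 11, 59541568 to 59566956) was at 0.274 ± 0.097 FPKM in Normal, 6.09 ± 4.43 in DSS and 3.45 ± 4.56 in RJA, a difference of 2.24 in DSS (SE 0.73) with adjusted p = 0.0583, which did not pass. It passed without DSS 2, RJA 1 or RJA 3 (adjusted p = 0.0254, 0.0432 and 0.0114). Casp1 (-0.51, adjusted p = 0.349), Gsdmd (0.65, adjusted p = 0.154) and Il18 (-2.39, adjusted p = 0.0583) did not pass. Il18 passed without DSS 2 (-3.35, 0.00749) and without RJA 3 (0.0375), with adjusted p from 0.000143 to 0.177 over all alternatives. Casp4, Pycard and Il1b each lost the call without any 1 of the Normal libraries, DSS 1 or DSS 3, with adjusted p from 0.055 to 0.12, and Il1b also without RJA 2 (0.0531). Of 6 gasdermins tested, Gsdmc2 (-4.23), Gsdmc3 (-5.34) and Gsdmc4 (-4.66) fell and Gsdma rose (1.01), with the same counts adjusted over the list alone (camera adjusted p = 0.355).

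**Figure D2:**
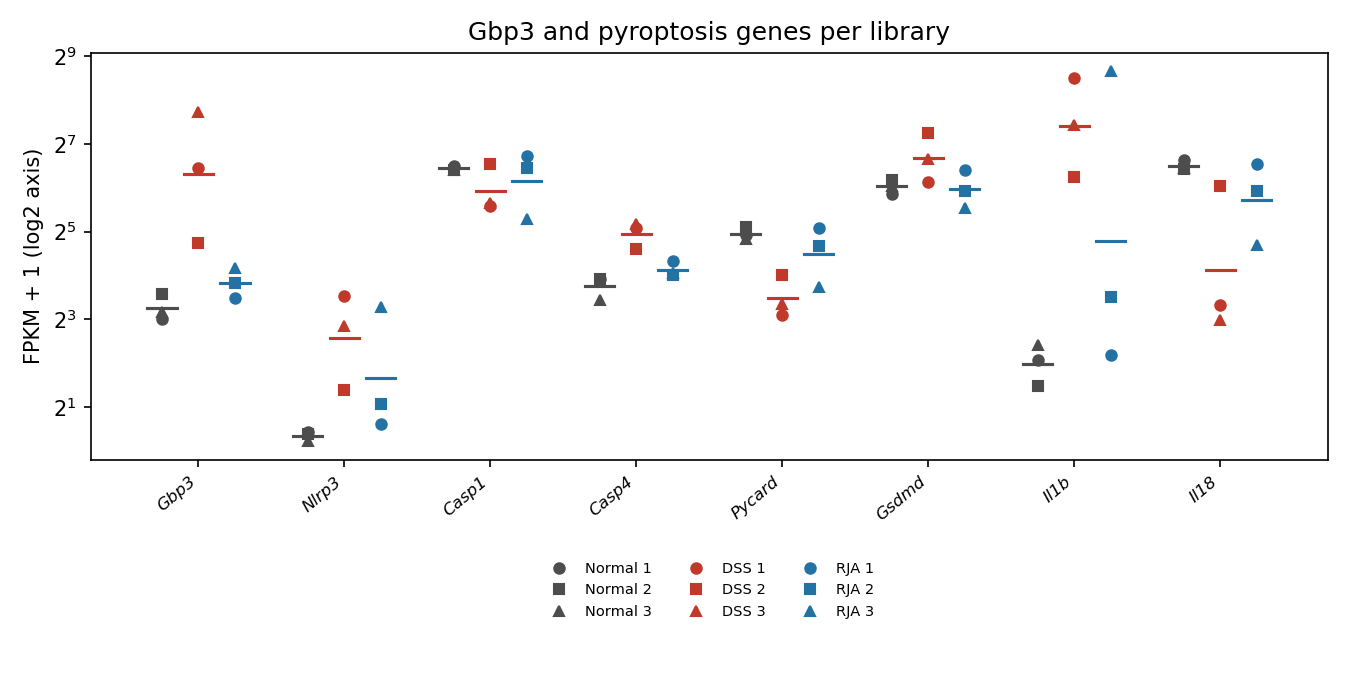
FPKM + 1 (y axis, log2 scale) of Gbp3 and 7 pyroptosis genes in each library; points are libraries and bars are geometric means of 3 libraries. All 3 RJA libraries lie below the lowest DSS library for Gbp3 (17.08 against 25.65 FPKM at the nearest), while RJA 3 (400.2 FPKM) lies above every DSS library for Il1b.

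RJA against DSS asks what royal jelly acid changed in DSS-treated colon. Among the genes called, Il22, a cytokine that acts on epithelium, was at 15.41 ± 3.48 FPKM in DSS and 0.964 ± 1.49 in RJA (SD, n = 3 each; log2 fold change -3.30, SE 0.44, limma adjusted p = 0.0339). Il18bp, the secreted inhibitor of IL-18, went from 41.11 ± 14.5 to 5.50 ± 1.96 FPKM (-2.69, SE 0.29, adjusted p = 0.0203), and the chemokine Ccl8 from 417.8 ± 104 to 115.3 ± 1.91 FPKM (-1.82, SE 0.19, adjusted p = 0.0203). Zbp1 (-2.00, adjusted p = 0.0339), Socs1 (-2.47, adjusted p = 0.0471) and Il12b (-1.25, adjusted p = 0.0409) also fell. The other large falls were in the lipase-related Pnliprp2 (-3.36, SE 0.21, adjusted p = 0.0015), Gml (-3.50), Bmp8b (-3.36), Gml2 (-2.81), Ly6c1 (-2.70) and Trim15 (-2.64). Among the largest rises were Baiap2l2 (2.59), the cystathionine synthase Cbs (2.54), Guca2b (2.50), Creb3l1 (2.12), the matrix gene Mfap4 (1.82), Synpo2 (1.34) and the creatine kinase Ckb (1.29).

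**Figure D3:**
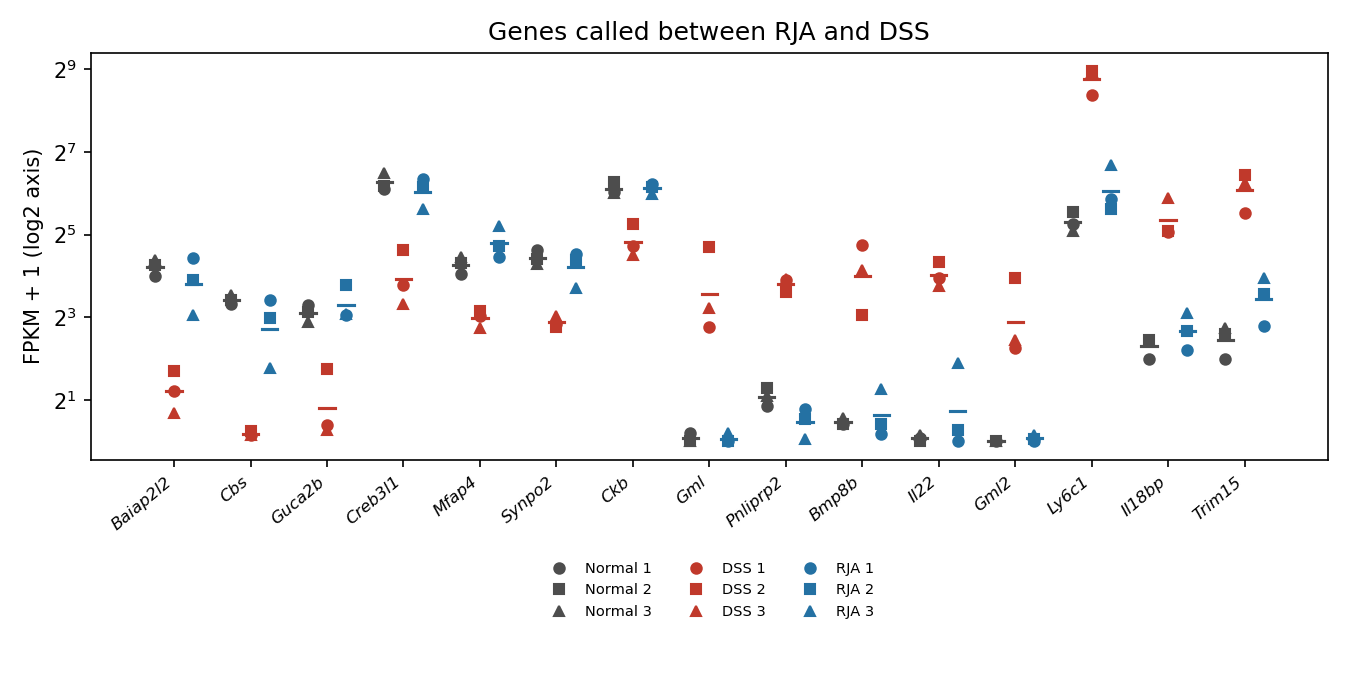
FPKM + 1 (y axis, log2 scale) of 7 of the 8 genes with the largest rise and the 8 with the largest fall among those called between RJA and DSS, per library, with bars at geometric means of 3 libraries. The libraries of RJA and DSS do not overlap for any of the 15 genes, by the rule that chose them.

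Interferon genes and several immune groups were lower in RJA than in DSS as sets by camera, while few of their members passed singly. Plasma cell markers (13 tested, camera adjusted p = 0.615) and mast cell and eosinophil markers (10 tested, 0.639) did not pass, with 0 members called either way. RJA 3 stood apart in several of them. It lay at 3.725 for cytokines and chemokines, above DSS 2 and DSS 3 (2.536 and 3.362), at 1.828 for macrophage markers, above DSS 2 (1.231), and at 4.807 for neutrophil markers, above all 3 DSS libraries. RJA 1 and RJA 2 lay below every DSS library in these 3 lists. Of 27 interferon-gamma genes, 1 fell and 26 did not pass (27 fell adjusted over the list alone, camera adjusted p = 2.57e-17, adjusted p = 0.52 with an estimated correlation), with Cxcl9 at -4.08 (SE 0.90) and Ido1 at -3.95 (SE 0.74). Of 24 type I interferon genes, 0 passed (11 fell adjusted over the list alone, camera adjusted p = 2.19e-10, adjusted p = 0.52 with an estimated correlation), with Ifit2 at -2.15. Of 25 cytokines and chemokines, 3 fell (4 adjusted over the list alone, camera adjusted p = 4.35e-08, adjusted p = 0.52 with an estimated correlation). Of 23 T and NK markers, 0 passed (4 fell adjusted over the list alone, camera adjusted p = 8.57e-08, adjusted p = 0.52 with an estimated correlation), with Gzma at -1.88. Of 21 macrophage markers, 0 passed (6 fell adjusted over the list alone, camera adjusted p = 0.000658, adjusted p = 0.584 with an estimated correlation). Of 18 neutrophil markers, 0 passed (1 fell adjusted over the list alone, camera adjusted p = 0.00179, 0.0672 without RJA 1, adjusted p = 0.597 with an estimated correlation). Of 5 erythroid markers, Alas2 fell (-1.39) and 5 fell adjusted over the list alone (camera adjusted p = 2.62e-06, adjusted p = 0.52 with an estimated correlation). The inflammasome list had 1 fall among 24, Zbp1 (1 rise and 3 falls adjusted over the list alone, camera adjusted p = 0.615), with Nlrp3 at -0.93 (adjusted p = 0.478), Casp1 at 0.23 (0.766), Casp4 at -0.81 (0.133), Pycard at 1.01 (0.194), Gsdmd at -0.72 (0.248), Il1b at -2.62 (0.329) and Il18 at 1.61 (0.28). Without RJA 3, Il1b (-4.55, adjusted p = 0.00639), Pycard (1.39, 0.0146) and Casp4 (-0.78, 0.047) passed, and Casp4 (-0.99, 0.0381) and Il18 (2.57, 0.0377) passed without DSS 2.

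Some epithelial groups and smooth muscle markers were higher in RJA than in DSS by camera, and other epithelial groups were lower. Of 14 enteroendocrine markers, Cck fell (-1.39, SE 0.19, adjusted p = 0.0371; 4 adjusted over the list alone, camera adjusted p = 0.000135). Of 19 wound-associated epithelium genes, 0 passed over all genes (1 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.00179). The 4 tuft cell markers were lower as a set with 0 passing either way (camera adjusted p = 0.0327). RJA 3 lay at -0.495 for enteroendocrine markers, below the Normal libraries, with RJA 1 and RJA 2 at 0.535 and 0.404, near DSS 3 at 0.684. For wound-associated genes it lay at 1.059, near DSS 2 at 1.063, and for tuft cell markers at 0.327, above DSS 2 at 0.275. For each of these 3 lists, adjusted p = 0.52 with an estimated correlation; they and Cck were chosen for this comparison after their values were seen. Of 21 cholesterol biosynthesis genes, 0 passed over all genes and 16 rose adjusted over the list alone (camera adjusted p = 4.68e-11, adjusted p = 0.52 with an estimated correlation), with Idi1 at 1.30 (SE 0.25) and Mvd at 1.21 (SE 0.26). For this list RJA 3 lay at -0.292, near DSS 2 at -0.32, with RJA 1 and RJA 2 at 0.403 and 0.209. Of 17 smooth muscle markers, Synpo2 and Pgm5 rose (15 adjusted over the list alone, camera adjusted p = 1.35e-10, adjusted p = 0.52 with an estimated correlation), with Actg2 at 2.05 (SE 0.40). Of 23 xenobiotic metabolism genes, 0 passed (6 rose adjusted over the list alone, camera adjusted p = 3.09e-07, adjusted p = 0.581 with an estimated correlation), with Cyp2c55 at 5.33 (SE 1.29), Gstm3 at 3.08 (SE 0.80) and Fmo5 at 1.40 (SE 0.34). Of 16 goblet markers, Creb3l1 rose (1 adjusted over the list alone, camera adjusted p = 0.00341, adjusted p = 0.597 with an estimated correlation), with Atoh1 at 2.97 (SE 0.86). Of 20 colonocyte markers, Guca2b rose (3 adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.642 with an estimated correlation), and this list lost its call without DSS 1, RJA 1 or RJA 2 (0.134, 0.157 and 0.0524). For this list RJA 3 lay at -2.77, near DSS 1 and DSS 3 (-2.98 and -2.67), while RJA 1 and RJA 2 lay at 0.006 and -0.51. For the goblet list RJA 3 lay at -1.903 and DSS 2 at 0.261. In the xenobiotic list they lay at -2.456 and -1.529. RJA 3 was thus below DSS 2 in all 3 of these lists.

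In all, 30 genes were higher and 43 lower in RJA than in DSS, 41.1% of the calls higher; with TPM scaling 53.4% were higher. Leaving out 1 library gave 0 higher and 3 lower (without Normal 1, Normal 3 or RJA 1), 0 and 4 (Normal 2 or DSS 3), 0 and 8 (DSS 1), 1 and 3 (RJA 2), 275 and 321 (DSS 2) and 1868 and 1545 (RJA 3). Pnliprp2 was the 1 named gene of 22 called that kept its call whichever library was left out. An unadjusted p under 0.05 was reached by 3178 genes.

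Of the genes called in DSS against Normal, 70 were called in the opposite direction in RJA against DSS, 43 raised then lowered and 27 lowered then raised, and 0 in the same direction. Il22, Ccl8, Zbp1 and Socs1 were among the former and Guca2b, Creb3l1, Synpo2 and Pgm5 among the latter. Independent lists of these sizes would share 7.83 genes in opposite directions, and simulated groups with no change that share the DSS libraries gave a median of 0 (at most 1 in 100 draws), with few genes called in either comparison. With the measured DSS change kept and RJA set to the DSS mean, a simulation added after seeing the data, the median was again 0 and the highest of 100 draws 4. At most 6 genes were then called in RJA against DSS, so neither simulation sets the overlap that 73 calls would have. The covariance of the 2 sets of log2 fold changes across genes was -0.489, against a simulated median of -0.0519 (-0.266 to 0.131), a difference of -0.437; genes are not independent replicates, and part of the excess may come from the shared DSS libraries. The number of genes was 3 without Normal 1, Normal 2, Normal 3 or RJA 1, 4 without DSS 3 or RJA 2, 8 without DSS 1, 588 without DSS 2 and 3197 without RJA 3. With each DSS library held out of gene choice, the RJA mean lay 60.57%, 38.76% and 62.43% of the way from the held-out library (DSS 1, 2 and 3) to Normal, over 170, 5037 and 149 genes. The median of these was 60.6% (SD 13.2, n = 3), 45.4% without RJA 1 and 84.7% without RJA 3. The 3 values share the RJA and Normal means and use overlapping DSS libraries, so this SD does not measure the spread between samples. With DSS 2 held out, RJA 1, 2 and 3 lay at 95.86%, 50.36% and -32.67%, so RJA 3 was farther from Normal than that DSS library.

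RJA against Normal asks what remained different under DSS with RJA. No gene passed in limma: 0 were higher and 0 lower, with 991 at an unadjusted p under 0.05 and a smallest adjusted p of 0.235; limma-voom also called 0. With no filter 1 was higher and 1 lower, 1 was higher without DSS 2 and without RJA 1, and gene-by-gene array weights, chosen after seeing the data, gave 471 and 447. The genes with the smallest p, given as values, were Dhrs9 (1.77, SE 0.24), Ccl8 (1.34, SE 0.19), the macrophage gene Gpnmb (1.58, SE 0.23) and Plet1 (3.36, SE 0.50) on the higher side, with adjusted p = 0.235 each. Cpm (-1.74, SE 0.32) and Ascl2 (-1.20, SE 0.23) on the lower side had adjusted p = 0.305. Of 21 macrophage markers, 0 passed over all genes and 13 rose adjusted over the list alone (camera adjusted p = 2.25e-15, adjusted p = 0.224 with an estimated correlation), with Trem2 at 1.28 (SE 0.18) and Adgre1 at 1.10 (SE 0.22). Of 10 mast cell and eosinophil markers, 7 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 3.09e-11, adjusted p = 0.0932 with an estimated correlation, fry adjusted p = 0.0107), with the mucosal mast cell proteases Mcpt1 (2.14, SE 0.42) and Mcpt2 (2.25, SE 0.44) and the eosinophil granule gene Prg2 (0.74, SE 0.14). In DSS against Normal, where this list was chosen for description after its values were seen, 5 of these 10 rose (5 adjusted over the list alone, camera adjusted p = 0.000118, adjusted p = 0.408 with an estimated correlation). Of 17 endoplasmic reticulum stress genes, 8 rose adjusted over the list alone (camera adjusted p = 3.09e-11, adjusted p = 0.224 with an estimated correlation), and of 13 plasma cell markers 5 (camera adjusted p = 4.27e-08, adjusted p = 0.224 with an estimated correlation). Camera called 16 lists higher in RJA than in Normal and 8 lower. Also higher were T and NK markers (camera adjusted p = 2.28e-10), cytokines and chemokines (3.47e-09), fibroblast markers (9.38e-08), neutrophil markers (3.36e-07) and interferon-gamma genes (7.55e-06). In each of these lists 0 members passed over all genes, and adjusted p = 0.483 with an estimated correlation. All but T and NK markers were chosen here after their values were seen. Guanylate-binding proteins (camera adjusted p = 0.0515) and type I interferon genes (0.477) did not pass. RJA 3 stood apart in the macrophage list (1.828, against 0.491 and 0.77 in RJA 1 and RJA 2) and in the endoplasmic reticulum stress list (0.758, against 0.358 and 0.308). It also did so in neutrophil markers (4.807, against 0.317 and 1.051) and in cytokines and chemokines (3.725, against 0.283 and 0.619). In interferon-gamma genes it did not (0.604, against 0.577 and 0.473). The colonocyte list was lower with 0 members passing either way (camera adjusted p = 0.000146, 0.19 without RJA 3, adjusted p = 0.572 with an estimated correlation). The inflammasome list did not pass (camera adjusted p = 0.541) but did without RJA 3 (0.0128).

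Across the 3 comparisons, camera with the preset correlation called 33, 28 and 24 of 42 lists (DSS against Normal, RJA against DSS, RJA against Normal), and with an estimated correlation 0, 0 and 0, with smallest adjusted p of 0.408, 0.52 and 0.0932. Fry called 24, 3 and 1. The 3 in RJA against DSS were interferon-gamma genes, smooth muscle markers and erythroid markers (fry adjusted p = 0.0477 each). Type I interferon genes (0.117), cholesterol biosynthesis (0.117), T and NK markers (0.169) and neutrophil markers (0.345) did not pass by fry there.

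The title also names miR-210-3p. These libraries were made from poly-A selected mRNA and do not measure mature miRNAs. The precursor gene Mir210 had 3, 5 and 2 rebuilt fragments in the RJA libraries, 0 in each DSS library and 0, 0 and 1 in the Normal libraries. The total was 11. Its difference did not pass in RJA against DSS (limma adjusted p = 0.0667) or in RJA against Normal (adjusted p = 0.342). Counts this low are imprecise. Of 14 tested genes reported elsewhere as miR-210-3p targets, Gpd1l (-1.24, SE 0.20) and Efna3 (-0.74, SE 0.17) fell and Ptpn1 rose (1.57, SE 0.39) in DSS, with the same counts adjusted over the list alone (camera adjusted p = 0.29). In RJA against DSS 0 passed (1 rose adjusted over the list alone, camera adjusted p = 0.407).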

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

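Gene-by-gene array weights and all alternatives for the held-out measure were chosen after seeing the data. Of the alternative values for named genes, 4584 kept direction and side of the threshold, 226 passed only in the alternative, 901 no longer passed and 5 reversed. For lists these were 1118, 12, 74 and 4. Median-ratio scaling and quantile normalization kept all counts within 1.5 times. With a pseudocount of 0.1, RJA against DSS had 15 genes higher and 20 lower, and 33 genes moved back, meaning called in opposite directions in both DSS comparisons. With no filter, which tests more genes, DSS against Normal had 789 and 849, RJA against DSS 7 and 20, RJA against Normal 1 and 1, and 24 moved back. With a mean FPKM of at least 5, which tests fewer genes, 1141 were lower in DSS than in Normal, RJA against DSS had 6 and 15, and 21 moved back. TPM scaling gave 27 lower in RJA than in DSS. With only the 2 groups compared, 2590 were higher in DSS than in Normal, RJA against DSS had 0 and 2, and 2 moved back. For RJA against DSS this fit leaves out the Normal libraries, which had the lowest spread, and rests on fewer libraries. The cause of these changes was not tested. With limma-voom on rebuilt fragments RJA against DSS had 5 and 14, and 19 moved back. With the sample number as a replicate block, RJA against DSS had 0 and 5, and 5 moved back; the samples share only a number. Samples with the same number were also correlated after the mean of each group was subtracted from every gene, which leaves only differences within groups. These correlations were 0.04, 0.057 and 0.054 for DSS and Normal. They were -0.499, 0.292 and 0.3 for RJA and DSS, and 0.016, -0.101 and -0.073 for RJA and Normal. By this measure each of the 3 DSS samples correlated best with the Normal sample of its own number, but at 0.057 or less. In RJA and DSS 1 of 3 did, and in RJA and Normal 0 of 3. Without the subtraction, DSS 1 and DSS 3 correlated better with Normal 2 (0.809 and 0.821) than with Normal 1 and Normal 3 (0.795 and 0.811, in that order). These values do not show a pairing, and the labels give none. A log2 fold change of at least 1, which only removes calls, left 1000 and 947 in DSS against Normal and 18 higher in RJA than in DSS.

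The default estimate of limma array weights stopped before converging, so its values are given without weight: 4525 higher and 4718 lower in DSS than in Normal, and 22 lower in RJA than in DSS. Gene-by-gene weights gave 4340 and 4556 in DSS against Normal, 4003 and 3984 in RJA against DSS, 471 and 447 in RJA against Normal, and 6833 moved back. Those weights were lowest for RJA 3 (0.188) and DSS 2 (0.213), the libraries apart from their groups, so these counts are no evidence of a larger effect. For lists, camera with an estimated correlation called 0, 0 and 0 in the 3 comparisons, and fry called 3 in RJA against DSS and 1 in RJA against Normal. Except where the settings' construction is named above, the cause was not tested.

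Leaving out each library in turn gave 43 to 2705 genes higher and 14 to 2814 lower in DSS than in Normal, 0 to 1868 higher and 3 to 1545 lower in RJA than in DSS, 0 to 1 higher in RJA than in Normal, and 3 to 3197 moved back; the cause was not tested. The lowest counts in DSS against Normal came without Normal 1, while several libraries shared the lowest in the others. The highest came without RJA 3, except that 1 gene was higher in RJA than in Normal without DSS 2 and without RJA 1. The held-out share ran from 45.41% without RJA 1 to 84.68% without RJA 3. Some values that were never called in the full set turned direction. Gsdmd in RJA against Normal was 0.124 with limma array weights and ran from -0.292 (without RJA 1) to 0.145 (without RJA 3), and was 0.008 without Normal 2. Casp1 ran from -0.06 (without RJA 1) to 0.659 (without RJA 3) in RJA against DSS, and from -0.573 (without RJA 1) to 0.147 (without RJA 3) in RJA against Normal. The inflammasome list turned in RJA against DSS with limma array weights (adjusted p = 0.903), gene-by-gene weights (0.823) and without RJA 3 (0.774), over a range of 0.289 to 0.818 without 1 library. In RJA against Normal it turned without RJA 1 (0.802), over a range of 0.0128 to 0.831; the cause was not tested. Genes near the filter rest on few fragments, and how large a difference could be detected there was not measured.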

Other observations

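The tests on RJA replicate 3 were chosen only after the result was seen, and the hypoxia and circadian lists were chosen for description after their values were seen. Enteroendocrine cells are an epithelial lineage, and their markers were higher in DSS by camera while the absorptive colonocyte and goblet lists of the report were lower. Of 14 enteroendocrine markers, 5 rose (5 adjusted over the list alone, camera adjusted p = 0.000924, adjusted p = 0.408 with an estimated correlation), among them the hormone genes Sct (1.95, SE 0.34) and Cck (1.34, SE 0.19) and the serotonin synthesis gene Tph1 (1.45, SE 0.38). Of 19 enteric neuron and glia markers, 8 rose (14 adjusted over the list alone, camera adjusted p = 9.08e-06, adjusted p = 0.408 with an estimated correlation), with the glial genes Gfap (1.95, SE 0.33) and Sox10 (0.85, SE 0.21). Of 24 hypoxia response genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.185, 0.034 without DSS 1 and 0.888 without DSS 2, the range over all alternatives), with Hk2 (1.46, SE 0.29), Slc2a1 (0.77, SE 0.17), Hif1a (1.11, SE 0.24) and Adm (1.23, SE 0.28) among the rises. Of 14 circadian clock genes, 2 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.648). The clock activators Arntl (-1.62, SE 0.21), Npas2 (-1.85, SE 0.43) and Clock (-0.90, SE 0.21) fell, and Tef (0.84, SE 0.21) and Dbp (1.35, SE 0.39) rose; the labels give no hour of sampling.

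RJA 3 had neutrophil genes at the DSS level on average and interferon-gamma genes below it. Not every neutrophil marker followed: in RJA 3 S100a9 was at 1690 FPKM, above every DSS library, and Ly6g at 115 FPKM, below every DSS library. For neutrophil markers it lay at 4.81 (log2, relative to Normal) against 4.23, 2.74 and 3.60 in DSS, and for interferon-gamma genes at 0.60 against 2.47, 1.45 and 3.07, with 0.209 FPKM of Ifng against 4.30, 0.833 and 15.6; RJA 1 and RJA 2 lay at 0.577 and 0.473 for interferon-gamma genes, so that level was not particular to RJA 3. Library scaling is argued against, since 1 factor per library moves all genes in the same direction. RJA 3 lay above every DSS library in neutrophil markers and below every one in interferon-gamma genes. With 1 added to the FPKM, the lists need not move by equal amounts. The interferon-gamma score minus the neutrophil score of RJA 3 lay 2.443 below the lowest DSS library (SD of the DSS libraries 0.623). That difference restates the pattern and is no separate test. Fewer T and NK cells stay open: the mean of their markers lay 0.055 below the lowest DSS library, but 10 of 23 members lay below it and 13 did not, with Nkg7 1.049 and Gzma 0.813 below and Gzmb above. A DSS library labelled as RJA stays open: RJA 3 lay below both other DSS libraries in a median of 50% of the 50 most reproducible DSS-raised genes, but the held-out DSS 2 did so in 90%, so its bound, 20 points above the highest, could not be reached. An effect of RJA also stays open, as untested.

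Inflammasome genes listed as epithelial were lower in DSS, with a median log2 fold change of -1.463 over 13 genes. Library scaling is argued against for this fall relative to other genes, since 1 factor per library moves all genes in the same direction. With 1 added to the FPKM, genes of low FPKM move less. In DSS against Normal all tested genes had a median of -0.005, and interferon-gamma genes a median of 1.77. The planned test adds nothing to this: the median-ratio factors (0.9997 to 1.016) moved almost nothing, and the median of -1.458 after that scaling was bound to stay. Loss of epithelial cells may account for the median of the 13 genes, since it lay between the quartiles of 19 pan-epithelial genes (-1.558 and -0.895). The 13 genes were spread more widely, with quartiles of -3.302 and -0.743, so the medians alone do not show that the list moved like epithelial loss. The lower quartile lay beyond the lowest pan-epithelial gene (-2.503). Gsdmc2, Gsdmc3 and Gsdmc4 (-4.23, -5.34 and -4.66) were among the genes past that gene, so a change in such genes or in mature colonocytes stays open.

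Of 7 posterior HOX genes, which mark the distal gut, 4 fell and 1 rose in DSS (6 and 1 adjusted over the list alone, camera adjusted p = 0.0106, adjusted p = 0.411 with an estimated correlation), with Hoxb13 at -3.20 (SE 0.82) and Hoxd12 at -2.39 (SE 0.38). Tissue taken nearer the proximal end stays open. The test expected 11 anterior HOX genes to rise in that case, and as a set they did not (median -0.319, upper quartile 0.229). Whether these genes are higher in more proximal colon is not known from these data, so the test cannot decide. Loss of epithelial cells cannot be told apart from a change within cells: the posterior HOX median of -1.696 lay just past the pan-epithelial lower quartile of -1.558, by less than its own quartile range (-2.114 to -1.248).

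Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. In DSS against Normal, 1 of 10 splits called as many genes as the real one (3415, highest other 0). In RJA against DSS, 2 of 10 did (real 73, highest other 3635); the other was DSS 1, DSS 3 and RJA 3 against DSS 2, RJA 1 and RJA 2. That split calls many times the real count and points to a structure of the samples, in which DSS 2 and RJA 3 lie apart from their groups. The lists differed in this. In goblet markers DSS 2 (0.261) and RJA 3 (-1.903) lay on the side of the opposite group. In interferon-gamma genes (1.451 and 0.604) and erythroid markers (2.626 and -0.199) they lay on the side of their own group. An exchange of these libraries or animals that differ in severity stays open. In RJA against Normal, 10 of 10 did (real 0, highest other 1).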
